A study of Mus musculus with 12 samples.

How the data were processed

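Total liver RNA of 12 male C57BL/6 mouse samples (3 for each of wild type and Lampe1 on chow and on HFHC) was isolated with Trizol and a cleanup kit and made into Illumina TruSeq libraries, per the labels. The deposited values were RPKM per gene symbol, per the file headers, in 1 file per sample with 25225 rows in the same order. The submitters' processing notes named Cufflinks, without a version, and the mouse build mm8. The aligner, the annotation, the filters and the denominators of the RPKM are not given in the sources used here. Before the data were examined FPKM had been assumed because Cufflinks was named. The files held RPKM, to which the same test applies. A reference of a later mouse build was not used here, and no coordinates are given. Samples were grouped by the titles in the labels. Groups, tests, gene lists and the alternatives named below as fixed beforehand were set before the data were examined.

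Rows without a gene symbol (3242) were left out of the tests. They held 3.74 to 5.90% of the RPKM in 6 libraries and 21.0 to 29.1% in the other 6, and this split, found in the data and set at 10%, defined the low and the high library set. Rows that shared a symbol (574 symbols) were summed, and 524 rows that named several genes were kept as they were, which gave 21299 symbols. Genes with at least 1 RPKM in at least 3 of the 12 samples, 11335 in number, were tested. Of these 223 were listed at 0 in at least 1 library. For such genes values per library are given, with no mean or fold. Genes with near-identical copies (Mup, Cyp2c, Cyp4a, Gsta, Serpina1 and Acot families) can share reads, so their single values are uncertain.

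The authors' RPKM carry no read counts, so the absolute depth, and with it the counting error of a value, is unknown. Ratios of values under 0.5 RPKM between 2 libraries should pile up at whole-read steps if values come from counts. The commonest step, in bins of 0.01 log2 units, held a median of 2.67% of rows for the 30 pairs within a set and 0.987% for the 36 pairs between the sets. The steps gave relative depths of 1 to 2.71 within the low set and 1 to 3.27 within the high set, and the sets could not be joined. No whole reads were recovered.

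The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts of group means, eBayes with trend), two-sided, on log2(RPKM + 1), with all 12 samples and 4 group means in 1 fit. Fold changes are on that scale, which understates the change of low genes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 per contrast. The contrasts were Lampe1 against wild type on chow and on HFHC, HFHC against chow in wild type and in Lampe1, and the genotype by diet interaction, which is the diet response in Lampe1 minus that in wild type. Simulations tested the scripts with 200 of 11335 genes changed and no shift of most genes. For the genotype on chow 84% of 2-fold and 49% of 1.5-fold changes were found, with 8 false calls among 147. For the wild-type diet these were 86% and 50%, with 4 among 145. The 30 gene lists, fixed from textbook knowledge of liver, were tested with camera at a preset correlation of 0.01 and again with an estimated one, with adjustment over the lists in each contrast. Camera compares a list with all other genes. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

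The rule for named genes took, per group contrast, the 8 largest rises and 8 largest falls among genes past the threshold with no overlap between the 3 and 3 samples and a group mean of at least 5 RPKM, without names that are clone or model numbers. It added Acox1, up to 4 members of each list with the smallest adjusted p and up to 2 members not past the threshold with the highest mean. For the interaction it took the 10 smallest adjusted p. The rule gave 682 pairs of gene and contrast, of which 414 passed the threshold and 365 did so on both scales. Of these, 231 were followed through the alternatives, 208 past the threshold and 207 on both scales, and the text takes its examples from these 231. This choice was made after the values were seen and mostly among genes past the threshold on both scales, so the examples show changes more often than the rule as a whole.

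The alternatives fixed beforehand were a pseudocount of 0.1 RPKM, no filter, a mean of at least 5 RPKM, quantile normalization, upper-quartile scaling, the replicate number as a block, only the 6 samples of a comparison, sample weights, the highest row per symbol, each sample left out in turn, a fold of at least 2, the estimated correlation, and limma's fry, which tests whether a list moves one way. Added after the data were seen were a term for the library set with and without upper-quartile scaling, each set alone, genes listed at 0 left out, and scaling to the rows left after the 100 most abundant. A set alone holds 1 or 2 samples per group, and a lone sample is assumed to vary like the others. Alternatives that need counts were not run because the files hold RPKM.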

Results

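Hepatic mRNA was profiled in 12 liver samples from male C57BL/6 mice killed at 12 weeks of age, in 4 groups of 3. Wild-type mice and mice carrying the Acox1Lampe1 mutation, called Lampe1 here, were fed regular chow for 12 weeks, or chow for 8 weeks and then a high-fat high-carbohydrate diet (HFHC) for 4 weeks. Fat supplied 13.5% of the energy in chow and 58% in HFHC, and carbohydrate 59% and 25.5%. Acox1 encodes acyl-CoA oxidase 1, the enzyme of the first step of peroxisomal beta-oxidation of very long-chain fatty acids, and the comparisons address its part in liver metabolism and inflammation during diet-induced fatty liver. The files gave RPKM for each gene, which are read numbers scaled by transcript length and by the library's mapped reads, and the RPKM of a sample summed to 341024 to 469711. Read numbers were not given and the absolute depth is unknown. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Group values are the mean ± SD of 3 samples.

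Acox1 itself was listed at 425, 326 and 452 RPKM in the wild-type chow samples and at 281, 272 and 286 RPKM in the Lampe1 chow samples. On HFHC it was listed at 450.0, 345 and 483 RPKM in wild type and at 259.8, 367 and 479 RPKM in Lampe1. The Lampe1 chow samples thus all lay below the wild-type chow samples, while the HFHC samples overlapped. The log2 fold change of Acox1, Lampe1 against wild type, was -0.50 ± 0.21 on chow (adjusted p = 0.0502) and -0.24 ± 0.21 on HFHC (adjusted p = 0.316). After each sample was scaled to the same upper quartile, the values were -1.08 (adjusted p = 0.00306) and -0.91 (adjusted p = 0.00401). Within the library sets described next, the unscaled fold changes were -0.41 and -0.68 on chow and -0.89 and 0.09 on HFHC. The labels do not describe the change in the mutant allele, and a change that alters the protein need not alter the mRNA, so these values check the genotype labels only in part. HFHC moved Acox1 past the threshold in neither genotype (0.09 ± 0.21, -0.01 scaled in wild type, 0.35 ± 0.21, 0.17 scaled in Lampe1).

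The share of RPKM held by the most abundant genes differed between the groups. The 100 most abundant named genes held 54.5 ± 2.22% of the named RPKM in wild type on chow and 36.1 ± 3.09% in Lampe1 on chow. On HFHC the shares were 48.4 ± 6.00% and 29.2 ± 1.62%. The median log2 fold change of the 11335 tested genes was 0.51 for the genotype on chow, 0.66 for the genotype on HFHC, 0.08 for the diet in wild type, 0.23 for the diet in Lampe1 and 0.15 for the interaction. Scaling to the same upper quartile left medians of 0.06, 0.14, 0.01, 0.07 and 0.06. A gene or list is thus said to be higher or lower, or to rise or fall, only if it passed the same way on the deposited and scaled values. The word "scaled" marks a log2 fold change on the latter, and adjusted p belong to the deposited values. List counts follow this rule, which dropped more scaled falls than rises. List medians are relative to the median of all tested genes. The libraries also fell into 2 sets of 6. Rows without a gene symbol held 3.74 to 5.90% of the RPKM in the low set (WT chow 1 and 2, WT HFHC 3, Lampe1 chow 2 and 3, Lampe1 HFHC 1). The high set, with the other 6 libraries, had 21.0 to 29.1%. Each group had members in both sets, and pairs of values in brackets after a list median are those within the low and the high set. Alb, the serum albumin gene, was listed at 0 in WT HFHC 1 and 3 and at 9729.6 to 15821 RPKM in the other 10 libraries, so a 0 in these files can be a failed estimate. Mup1 was at 0 in the same pair of libraries. Alb and Mup1 are counted in the hepatocyte and male-biased lists.

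**Figure D1:**
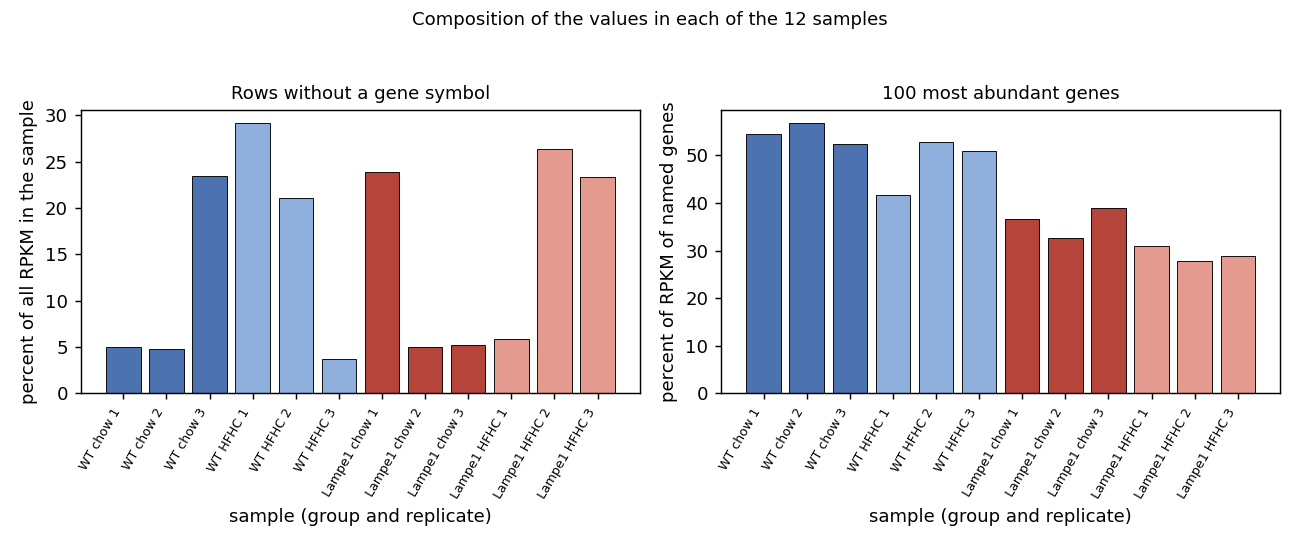
Left, percent of all RPKM in rows without a gene symbol in each of the 12 samples; right, percent of the named RPKM held by the 100 most abundant named genes in each sample. The left values fall into a low set (3.74 to 5.90%) and a high set (21.0 to 29.1%) with members of every group, and the right values are 52.3 to 56.7% in wild type on chow and 27.7 to 30.9% in Lampe1 on HFHC.

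On chow, 14 of 17 genes expressed at higher levels in male than in female liver were lower in Lampe1 than in wild type, a list call that held with an estimated correlation (adjusted p = 0.0119). Of the PPAR alpha targets 16 of 23 and of the lipid droplet and uptake genes 11 of 18 were higher, list calls that were lost with it (adjusted p = 0.295 and 0.473). Ehhadh, the peroxisomal bifunctional enzyme that acts after Acox1, averaged 50.5 ± 10.4 against 861 ± 38.7 RPKM (log2 fold change 4.09 ± 0.17, 3.51 scaled, adjusted p = 3.51e-08, wild type named first). Cyp4a10, a fatty acid hydroxylase and a classical target of the nuclear receptor PPAR alpha, averaged 86.8 ± 7.42 against 1267 ± 222 RPKM (log2 fold change 3.84 ± 0.26, 3.27 scaled, adjusted p = 1.20e-06), although reads can be shared within the Cyp4a family. Hsd3b5, a steroid dehydrogenase of male liver, fell from 66.7 ± 12.1 to 0.228 ± 0.0705 RPKM (log2 fold change -5.77 ± 0.17, -6.19 scaled, adjusted p = 3.25e-09). Of 11335 genes, limma called 7685 higher and 410 lower as deposited and 2053 and 1419 as scaled. Quantile normalization gave 1421 and 1380. On both scales 2053 and 410 passed, each scaled rise but not each scaled fall. Large rises included Fabp3, a fatty acid binding protein (0.627 ± 0.496 against 134 ± 14.0 RPKM, 6.07 scaled), Ly6d, a small membrane-anchored protein (0.641 ± 0.787 against 236 ± 7.38 RPKM, 6.97 scaled), and the hormone Fgf21 (0.612 ± 0.118 against 65.0 ± 45.1 RPKM, 4.77 scaled). At least 98.5% of the genes called higher, and of those called lower, on both scales had the same sign within each set, though these genes were chosen by their pooled calls. The median of all genes was 0.56 within the low and 0.40 within the high set. Quantile normalization ended the calls of the lipogenesis, endoplasmic reticulum stress, drug-metabolising, acute phase, hepatocyte, erythroid, pancreas, adipose and muscle and circadian clock lists.

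**Figure D2:**
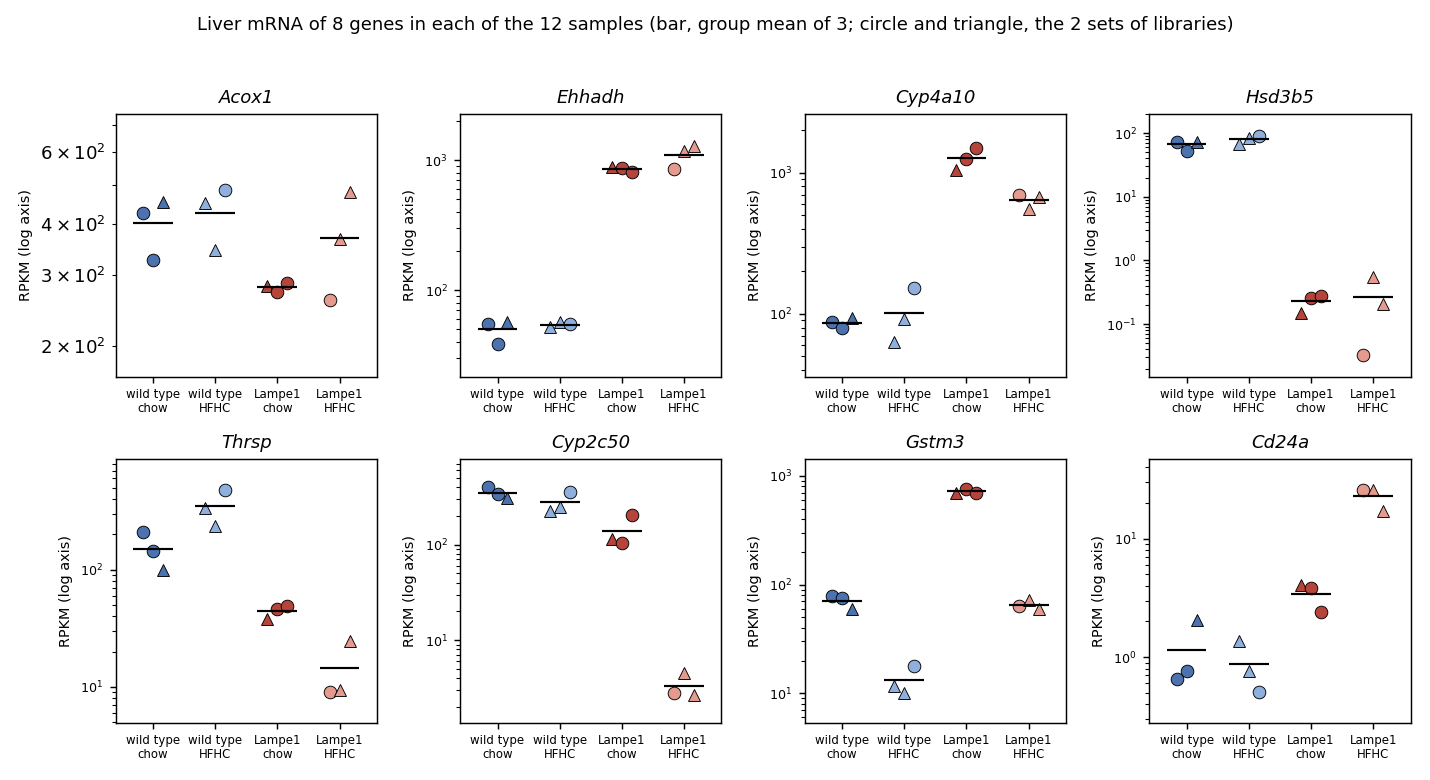
RPKM (log axis) of Acox1, Ehhadh, Cyp4a10, Hsd3b5, Thrsp, Cyp2c50, Gstm3 and Cd24a in each of the 12 samples by group, with a bar at the mean of the 3 samples, circles for libraries of the low set and triangles for the high set. Ehhadh averages 50.5 ± 10.4 and 54.4 ± 2.21 RPKM in wild type on chow and HFHC and 861 ± 38.7 and 1106 ± 221 RPKM in Lampe1, and Gstm3 is lower on HFHC in both genotypes.

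The list of mitochondrial fatty acid oxidation and ketogenesis counted 8 higher of 21 (20 as deposited, 20 adjusted over the list alone). Their median was 0.38 (0.37 and 0.31), with camera adjusted p = 0.000851 and adjusted p = 0.503 with an estimated correlation. Acot2, a mitochondrial acyl-CoA thioesterase, rose from 1.63 ± 0.598 to 108 ± 10.8 RPKM (4.96 scaled). Acaa2, the last enzyme of the cycle, was 307 ± 29.8 against 370.4 ± 38.7 RPKM (0.27, -0.31 scaled, adjusted p = 0.0906). PPAR alpha targets outside beta-oxidation counted 16 higher and 1 lower of 23 (20 and 1 as deposited, 20 and 1 adjusted over the list alone). Their median was 1.23 (1.21 and 1.2), with camera adjusted p = 0.00151 and adjusted p = 0.295 with an estimated correlation. The abundant Fabp1 was 4272 ± 356 against 5723 ± 394 RPKM (0.42, -0.16 scaled, adjusted p = 0.0798). Peroxisomal beta-oxidation and biogenesis genes counted 7 higher of 32 (23 as deposited, 23 adjusted over the list alone). Their median was 0.04 (0.10 and 0.03), with camera adjusted p = 0.406. Pex11a, a peroxisome proliferation factor, rose from 33.4 ± 4.02 to 116 ± 16.5 RPKM (1.2 scaled). Lipid droplet and lipid uptake genes counted 11 higher of 18 (15 as deposited, 15 adjusted over the list alone). Their median was 1.09 (1.17 and 1.13), with camera adjusted p = 0.0275 and adjusted p = 0.473 with an estimated correlation. The droplet protein Cidec rose from 2.65 ± 0.592 to 56.7 ± 6.38 RPKM (3.51 scaled). The call of this list was lost without WT chow 3 or Lampe1 chow 3, where adjusted p reached 0.0554. Lipogenesis genes had a call on the deposited values alone and counted 2 higher and 2 lower of 21 (8 and 2 as deposited, 7 and 2 adjusted over the list alone). Their median was -0.16 (-0.07 and -0.09), with camera adjusted p = 0.0188 and adjusted p = 0.473 with an estimated correlation. The desaturase Scd1 was 461 ± 128 against 671 ± 182 RPKM (0.55, -0.03 scaled, adjusted p = 0.0797). Cholesterol biosynthesis and SREBP2 targets counted 2 higher of 24 (11 as deposited, 11 adjusted over the list alone). Their median was 0.06 (-0.08 and 0.36), with camera adjusted p = 0.453. Gluconeogenesis and glycolysis genes counted 3 higher of 19 (7 as deposited, 7 adjusted over the list alone). Their median was -0.18 (-0.12 and -0.25), with camera adjusted p = 0.0564.

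Male-biased liver genes counted 0 higher and 14 lower of 17 (1 and 14 as deposited, 1 and 14 adjusted over the list alone). Their median was -2.95 (-3.02 and -2.84), with camera adjusted p = 1.36e-33 and adjusted p = 0.0119 with an estimated correlation. Of the 30 lists it was the only 1 whose call on chow held with an estimated correlation. The major urinary protein gene Mup3, whose reads can be shared with near-identical Mup genes, fell from 4603 ± 547 to 174 ± 165 RPKM (-5.73 scaled). Female-biased liver genes counted 6 higher of 14 (9 as deposited, 9 adjusted over the list alone). Their median was 0.40 (0.47 and 0.60), with camera adjusted p = 0.850. Camera ranked that list below other genes on the deposited values, against the sign of its median, and above them on the scaled ones (adjusted p = 0.0268). Bile acid synthesis and transport genes counted 2 higher and 7 lower of 17 (4 and 7 as deposited, 4 and 7 adjusted over the list alone). Their median was -0.67 (-0.67 and -1.11), with camera adjusted p = 7.61e-09 and adjusted p = 0.10 with an estimated correlation. Drug-metabolising enzymes counted 1 higher and 7 lower of 19 (2 and 7 as deposited, 2 and 7 adjusted over the list alone). Their median was -0.57 (-0.70 and -0.82), with camera adjusted p = 6.37e-10 and adjusted p = 0.10 with an estimated correlation. Cyp3a11 was 2052 ± 351 against 1965 ± 322 RPKM (-0.06, -0.64 scaled, adjusted p = 0.795). NRF2 and glutathione defence genes counted 8 higher and 1 lower of 20 (13 and 1 as deposited, 14 and 1 adjusted over the list alone). Their median was 0.30 (0.23 and 0.48), with camera adjusted p = 0.192. The glutathione transferase Gstm3 rose from 71.2 ± 10.5 to 718 ± 38.3 RPKM (2.75 scaled) and sulfiredoxin, Srxn1, from 7.52 ± 1.23 to 45.2 ± 3.27 RPKM (1.91 scaled). Gstm1 was 1745 ± 266 against 2242 ± 155 RPKM (0.37, -0.21 scaled, adjusted p = 0.0512). Endoplasmic reticulum stress genes counted 4 higher and 3 lower of 23 (5 and 3 as deposited, 5 and 3 adjusted over the list alone). Their median was -0.69 (-0.70 and -0.63), with camera adjusted p = 4.66e-07 and adjusted p = 0.177 with an estimated correlation. Before the median of all genes was subtracted, their median log2 fold change was -0.19 and their mean 0.30. Its higher members included the ATF4 targets Trib3 (2.65 ± 2.25 against 55.0 ± 10.4 RPKM, 3.66 scaled) and asparagine synthetase, Asns (0.886 ± 0.590 against 7.88 ± 2.31 RPKM, 1.90 scaled). The chaperone Hspa5 was 166 ± 78.4 against 124 ± 18.6 RPKM (-0.33, -0.91 scaled, adjusted p = 0.357). Hepatocyte markers counted 0 higher and 6 lower of 16 (1 and 6 as deposited, 0 and 3 adjusted over the list alone). Their median was -0.72 (-0.80 and -0.87), with camera adjusted p = 1.00e-10 and adjusted p = 0.0972 with an estimated correlation. Serpina1a fell from 3648 ± 61.9 to 1037 ± 316 RPKM (-2.44 scaled) and transthyretin, Ttr, from 3026 ± 249.7 to 1776 ± 336 RPKM (-1.36 scaled, but 0.24 after quantile normalization).

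Recruited macrophage and monocyte markers counted 13 higher and 1 lower of 14 (13 and 1 as deposited, 13 and 1 adjusted over the list alone). Their median was 1.39 (1.29 and 1.49), with camera adjusted p = 0.00471 and adjusted p = 0.418 with an estimated correlation. The tetraspanin Cd9 rose from 8.40 ± 1.78 to 34.9 ± 0.559 RPKM (1.42 scaled). Kupffer cell markers counted 11 higher of 13 (12 as deposited, 12 adjusted over the list alone). Their median was 0.87 (0.74 and 1.21), with camera adjusted p = 0.00876 and adjusted p = 0.490 with an estimated correlation. Cytokines, chemokines and receptors counted 10 higher of 17 (14 as deposited, 14 adjusted over the list alone). Their median was 0.42 (0.25 and 0.49), with camera adjusted p = 0.308, 0.00818 on the scaled values, and adjusted p = 0.791 with an estimated correlation. Acute phase genes counted 5 higher and 6 lower of 22 (8 and 6 as deposited, 8 and 4 adjusted over the list alone). Their median was -0.47 (-0.60 and -0.04), with camera adjusted p = 4.04e-05 and adjusted p = 0.0893 with an estimated correlation. Their mean log2 fold change was 0.62. Apcs, serum amyloid P, rose from 23.8 ± 3.35 to 237 ± 67.3 RPKM (2.67 scaled) and metallothionein 1, Mt1, from 6.54 ± 2.91 to 182 ± 66.0 RPKM (4.09 scaled). Interferon-stimulated genes had a call on the deposited values alone and counted 2 higher and 1 lower of 21 (7 and 1 as deposited, 6 and 1 adjusted over the list alone). Their median was -0.34 (-0.43 and -0.17), with camera adjusted p = 0.00471 and adjusted p = 0.150 with an estimated correlation. Cell cycle genes counted 13 higher and 1 lower of 24 (20 and 1 as deposited, 21 and 1 adjusted over the list alone). Their median was 0.28 (0.23 and 0.44), with camera adjusted p = 0.133, 0.000190 on the scaled values, and adjusted p = 0.692 with an estimated correlation. Extracellular matrix and stellate cell markers counted 11 higher of 20 (18 as deposited, 19 adjusted over the list alone). Their median was 0.42 (0.44 and 0.25), with camera adjusted p = 0.137, 0.00149 on the scaled values, and adjusted p = 0.791 with an estimated correlation. Endothelial markers counted 0 higher of 13 (9 as deposited, 9 adjusted over the list alone, limma, 10 at an unadjusted p under 0.05). Their median was -0.06 (-0.01 and -0.19), with camera adjusted p = 0.953. Cholangiocyte and progenitor markers counted 2 higher of 11 (5 as deposited, 5 adjusted over the list alone). Their median was 0.11 (0.07 and 0.32), with camera adjusted p = 0.892. Neutrophil markers counted 2 higher of 4 (3 as deposited, 3 adjusted over the list alone). Their median was 0.29 (0.15 and 0.43), with camera adjusted p = 0.869. Immediate-early genes counted 2 higher of 11 (4 as deposited, 4 adjusted over the list alone). Their median was -0.15 (-0.28 and 0.35), with camera adjusted p = 0.0564. The single tested erythroid gene, Alas2, was lower (-2.09 scaled, list camera adjusted p = 0.00181, and adjusted p = 0.0893 with an estimated correlation). The T and NK cell list and the B cell list, with 1 tested gene each, had 0 genes past the limma threshold and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.754 and 0.710). The pancreas, adipose and muscle list counted 0 of 2 past the limma threshold on either scale or adjusted over the list alone and 0 at an unadjusted p under 0.05 and had a call on the deposited values alone (camera adjusted p = 0.0132, and adjusted p = 0.10 with an estimated correlation). The circadian clock list, also with a call on the deposited values alone, counted 0 of 14 past the limma threshold on either scale or adjusted over the list alone and 1 at an unadjusted p under 0.05. Their median was -0.08 (0.65 and -1.19), with camera adjusted p = 0.00124 and adjusted p = 0.0972 with an estimated correlation.

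On HFHC, 14 of 17 male-biased, 11 of 17 bile acid and 13 of 19 drug-metabolising genes were lower in Lampe1 than in wild type, list calls that held with an estimated correlation (adjusted p = 0.0373, 0.0496 and 0.0496). Of the lipogenesis genes 10 of 21 and of the cholesterol genes 10 of 24 were lower, list calls that were lost with it (adjusted p = 0.0512 and 0.200). Ehhadh averaged 54.4 ± 2.21 against 1106 ± 221 RPKM (log2 fold change 4.30 ± 0.17, 3.63 scaled, adjusted p = 8.82e-09) and Hsd3b5 81.0 ± 12.1 against 0.262 ± 0.262 RPKM (log2 fold change -6.03 ± 0.17, -6.39 scaled, adjusted p = 1.56e-09). Thrsp, a protein that promotes lipogenesis, fell from 349.8 ± 122 to 14.3 ± 8.86 RPKM (log2 fold change -4.60 ± 0.37, -5.24 scaled, adjusted p = 9.65e-07), and Cyp2c50, a cytochrome P450 of a family with similar members, from 276 ± 71.6 to 3.32 ± 1.06 RPKM (log2 fold change -6.00 ± 0.26, -6.57 scaled, adjusted p = 1.95e-08). Krt23, a keratin, rose from 1.43 ± 0.602 to 20.9 ± 2.40 RPKM (log2 fold change 3.20 ± 0.18, 2.66 scaled, adjusted p = 7.35e-08). limma called 8200 genes higher and 856 lower as deposited and 3793 and 2095 as scaled. Quantile normalization gave 2970 and 2457. On both scales 3793 and 856 passed. At least 99.8% of the genes called higher, and of those called lower, on both scales had the same sign within each set. They too were chosen by pooled calls. The median of all genes was 0.65 and 0.68 within the sets. Quantile normalization ended the calls of the gluconeogenesis, endoplasmic reticulum stress, acute phase, erythroid, pancreas, adipose and muscle and circadian clock lists. Large rises included the lysosomal membrane protein Cd63 (3.19 ± 1.91 against 239 ± 41.2 RPKM, 5.32 scaled), Igfbp1, a binding protein of insulin-like growth factors (14.9 ± 4.53 against 608 ± 119.7 RPKM, 4.63 scaled), and Psat1, an enzyme of serine synthesis (0.362 ± 0.231 against 51.7 ± 15.4 RPKM, 4.79 scaled).

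Lipogenesis genes counted 2 higher and 10 lower of 21 (4 and 10 as deposited, 4 and 9 adjusted over the list alone). Their median was -1.23 (-1.09 and -1.04), with camera adjusted p = 2.27e-08 and adjusted p = 0.0512 with an estimated correlation. Cholesterol biosynthesis and SREBP2 targets counted 0 higher and 10 lower of 24 (3 and 10 as deposited, 2 and 9 adjusted over the list alone). Their median was -1.10 (-1.36 and -0.93), with camera adjusted p = 2.37e-11 and adjusted p = 0.200 with an estimated correlation. Bile acid genes counted 2 higher and 11 lower of 17 (3 and 11 as deposited, 3 and 11 adjusted over the list alone). Their median was -2.80 (-3.10 and -2.52), with camera adjusted p = 4.09e-14 and adjusted p = 0.0496 with an estimated correlation. Baat, which conjugates bile acids to amino acids, fell from 90.0 ± 10 to 12.6 ± 2.29 RPKM (-3.38 scaled). Drug-metabolising enzymes counted 2 higher and 13 lower of 19 (5 and 13 as deposited, 5 and 13 adjusted over the list alone). Their median was -2.17 (-3.06 and -1.72), with camera adjusted p = 9.07e-15 and adjusted p = 0.0496 with an estimated correlation. Male-biased genes counted 0 higher and 14 lower of 17 (1 and 14 as deposited, 1 and 14 adjusted over the list alone). Their median was -4.08 (-3.66 and -4.17), with camera adjusted p = 1.27e-23 and adjusted p = 0.0373 with an estimated correlation. Hepatocyte markers counted 2 higher and 11 lower of 16 (3 and 11 as deposited, 3 and 11 adjusted over the list alone). Their median was -1.69 (-1.79 and -1.58), with camera adjusted p = 7.65e-13 and adjusted p = 0.0496 with an estimated correlation. The 2 higher ones included Alb, listed at 0 in WT HFHC 1 and 3. Hpd, an enzyme of tyrosine breakdown, fell from 705 ± 92.2 to 136 ± 28.9 RPKM (-3.05 scaled). Gluconeogenesis and glycolysis genes counted 4 higher and 6 lower of 19 (6 and 6 as deposited, 6 and 6 adjusted over the list alone). Their median was -0.59 (-0.52 and -0.45), with camera adjusted p = 0.00107 and adjusted p = 0.219 with an estimated correlation. Mitochondrial fatty acid oxidation genes had a call on the deposited values alone and counted 8 higher of 21 (20 as deposited, 20 adjusted over the list alone). Their median was 0.09 (-0.13 and 0.19), with camera adjusted p = 0.0499 and adjusted p = 0.801 with an estimated correlation. The call was lost without 1 of 7 libraries, WT chow 1, WT HFHC 1, WT HFHC 2, Lampe1 chow 1, Lampe1 chow 2, Lampe1 chow 3 or Lampe1 HFHC 3, where adjusted p reached 0.104 and the median 0.0179.

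Extracellular matrix and stellate cell markers counted 17 higher of 20 (20 as deposited, 20 adjusted over the list alone). Their median was 0.73 (0.58 and 0.76), with camera adjusted p = 0.0493 and adjusted p = 0.801 with an estimated correlation. Col4a1 rose from 3.94 ± 1.36 to 28.6 ± 4.69 RPKM (2.01 scaled). The call of the matrix list was lost without WT HFHC 2, WT HFHC 3 or Lampe1 chow 1, where adjusted p reached 0.0742. Endoplasmic reticulum stress genes counted 4 higher and 9 lower of 23 (7 and 9 as deposited, 7 and 9 adjusted over the list alone). Their median was -0.92 (-0.66 and -1.15), with camera adjusted p = 6.22e-06 and adjusted p = 0.214 with an estimated correlation, and their mean log2 fold change 0.23. Acute phase genes counted 4 higher and 9 lower of 22 (8 and 9 as deposited, 8 and 9 adjusted over the list alone). Their median was -0.95 (-1.23 and -0.82), with camera adjusted p = 2.06e-06 and adjusted p = 0.0496 with an estimated correlation, and their mean log2 fold change 0.23. Interferon-stimulated genes counted 2 higher and 8 lower of 21 (7 and 8 as deposited, 7 and 8 adjusted over the list alone). Their median was -0.73 (-0.93 and -0.66), with camera adjusted p = 7.09e-05 and adjusted p = 0.0496 with an estimated correlation, and their mean log2 fold change 0.10. The erythroid gene Alas2 (-3.88 scaled, list camera adjusted p = 0.00262, and adjusted p = 0.0496 with an estimated correlation) was lower. The pancreas, adipose and muscle list counted 2 lower of 2 (2 as deposited, 2 adjusted over the list alone) and was lower (camera adjusted p = 0.00375, and adjusted p = 0.0496 with an estimated correlation), with Cfd at 18.1, 1.42 and 19.3 against 0, 0.287 and 0 RPKM. The circadian clock list had a call, lower, on the deposited values alone (camera adjusted p = 0.00152, and adjusted p = 0.0512 with an estimated correlation). PPAR alpha targets, without a call on the deposited values, counted 15 higher and 2 lower of 23 (19 and 2 as deposited, 19 and 2 adjusted over the list alone). Their median was 1.37 (0.78 and 1.5), with camera adjusted p = 0.281, 0.0194 on the scaled values, and adjusted p = 0.801 with an estimated correlation. Lipid droplet and uptake genes, also without one, counted 11 higher and 2 lower of 18 (13 and 2 as deposited, 13 and 2 adjusted over the list alone). Their median was 1.23 (0.95 and 0.98), with camera adjusted p = 0.457, 0.0202 on the scaled values, and adjusted p = 0.817 with an estimated correlation. Cell cycle genes, also without one, counted 20 higher and 1 lower of 24 (20 and 1 as deposited, 20 and 1 adjusted over the list alone). Their median was 0.39 (0.28 and 0.37), with camera adjusted p = 0.304, 0.00412 on the scaled values, and adjusted p = 0.817 with an estimated correlation. Recruited macrophage markers, also without one, counted 13 higher and 1 lower of 14 (13 and 1 as deposited, 13 and 1 adjusted over the list alone). Their median was 0.96 (0.70 and 1.07), with camera adjusted p = 0.0818, 0.000838 on the scaled values, and adjusted p = 0.718 with an estimated correlation. Cholangiocyte and progenitor markers counted 8 higher of 11 (10 as deposited, 10 adjusted over the list alone). Their median was 1.60 (1.53 and 1.58), with camera adjusted p = 0.0645, 0.00238 on the scaled values, and adjusted p = 0.718 with an estimated correlation. Cd24a rose from 0.880 ± 0.440 to 22.7 ± 4.82 RPKM (3.17 scaled).

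In wild-type livers, 8 of 20 NRF2 and glutathione genes fell on HFHC, a list call that held with an estimated correlation (adjusted p = 0.00202), and 4 of 21 lipogenesis genes rose, a call that was lost with it (adjusted p = 0.0740). Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 24.0 ± 0.548 to 353 ± 171 RPKM (log2 fold change 3.68 ± 0.32, 3.6 scaled, adjusted p = 0.000164, chow named first), and Elovl5, which elongates polyunsaturated fatty acids, from 68.7 ± 11.8 to 195 ± 34.3 RPKM (log2 fold change 1.49 ± 0.21, 1.40 scaled, adjusted p = 0.00712). Cyp3a11, a major drug-metabolising P450, fell from 2052 ± 351 to 220.4 ± 58.2 RPKM (log2 fold change -3.23 ± 0.20, -3.33 scaled, adjusted p = 2.34e-05), and Gstm1 from 1745 ± 266 to 437 ± 66.3 RPKM (log2 fold change -1.99 ± 0.16, -2.09 scaled, adjusted p = 0.000108). limma called 42 genes higher and 40 lower on the deposited values, 44 and 59 on the scaled ones, 34 and 50 after quantile normalization, and 39 and 40 on both. Every gene called on both scales had the same sign within both sets, though chosen by its pooled call. The median of all genes was 0.10 and 0.02 within the sets. Quantile normalization ended the calls of the male-biased and cell cycle lists. Other rises included Fabp2, an intestinal-type fatty acid binding protein (28.0 ± 2.35 against 84.4 ± 22.2 RPKM, 1.44 scaled), and the liver pyruvate kinase Pklr (31.3 ± 3.94 against 82.4 ± 11.6 RPKM, 1.28 scaled).

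Lipogenesis genes counted 4 higher of 21 (4 as deposited, 14 adjusted over the list alone). Their median was 0.81 (1.15 and 0.46), with camera adjusted p = 6.24e-13 and adjusted p = 0.0740 with an estimated correlation. The desaturase Fads1 rose from 59.8 ± 11.6 to 119 ± 27.0 RPKM (0.89 scaled). Cholesterol biosynthesis and SREBP2 targets counted 0 higher of 24 (0 as deposited, 20 adjusted over the list alone, limma, 20 at an unadjusted p under 0.05). Their median was 0.64 (1.01 and 0.45), with camera adjusted p = 4.58e-14 and adjusted p = 0.236 with an estimated correlation. NRF2 and glutathione defence genes counted 8 lower of 20 (8 as deposited, 9 adjusted over the list alone). Their median was -0.47 (-0.34 and -0.56), with camera adjusted p = 1.12e-25 and adjusted p = 0.00202 with an estimated correlation. Gstm3 fell from 71.2 ± 10.5 to 13.2 ± 4.05 RPKM (-2.49 scaled). Drug-metabolising enzymes counted 1 higher and 4 lower of 19 (1 and 4 as deposited, 1 and 5 adjusted over the list alone). Their median was -0.43 (-0.20 and -0.57), with camera adjusted p = 2.09e-09 and adjusted p = 0.172 with an estimated correlation. Interferon-stimulated genes counted 0 higher of 21 (0 as deposited, 8 adjusted over the list alone, limma, 8 at an unadjusted p under 0.05). Their median was 0.23 (0.25 and 0.32), with camera adjusted p = 9.06e-05 and adjusted p = 0.112 with an estimated correlation. Endoplasmic reticulum stress genes counted 0 of 23 past the limma threshold on either scale or adjusted over the list alone and 11 at an unadjusted p under 0.05. Their median was 0.39 (0.07 and 0.48), with camera adjusted p = 0.00947 and adjusted p = 0.746 with an estimated correlation. This call was lost without WT chow 1, WT chow 3 or WT HFHC 2, where adjusted p reached 0.25. The pancreas, adipose and muscle list, with Cela1 and Cfd as its tested genes, counted 0 higher of 2 (0 as deposited, 2 adjusted over the list alone, limma, 2 at an unadjusted p under 0.05). Their median was 1.17 (1.71 and 0.98), with camera adjusted p = 0.0301 and adjusted p = 0.172 with an estimated correlation. This call was lost without WT chow 3, WT HFHC 3 or Lampe1 chow 2, where adjusted p reached 0.168. Cfd, the adipose gene adipsin, was listed at 2.52, 1.01 and 1.87 on chow and 18.1, 1.42 and 19.3 on HFHC (RPKM, samples 1, 2 and 3), high in the libraries WT HFHC 1 and 3 that listed Alb and Mup1 at 0. Gluconeogenesis and glycolysis genes had a call, higher, on the scaled values alone (adjusted p = 0.0368, and 0.0501, or 0.746 with an estimated correlation, as deposited). Male-biased genes, Mup1 among them, and cell cycle genes had calls, lower, on the deposited values alone. The male-biased call (camera adjusted p = 0.0114, and adjusted p = 0.746 with an estimated correlation) was lost without WT chow 2 or WT HFHC 3, where adjusted p reached 0.109. The cell cycle call (camera adjusted p = 0.0478, and adjusted p = 0.746 with an estimated correlation) was lost without WT chow 2, WT chow 3, WT HFHC 1, WT HFHC 2 or Lampe1 chow 2, where adjusted p reached 0.150.

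The wild-type diet count of 82 genes was 31 without WT chow 1 and also 31 without WT chow 2, 53 without WT HFHC 1, 44 without WT HFHC 3, 52 with only the 6 wild-type samples in the fit and 425 with sample weights. Fads1 lost its call with only these 6 samples, and without WT chow 1, WT chow 2, WT HFHC 1 or WT HFHC 3, where adjusted p reached 0.113.

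In Lampe1 livers, 15 of 19 drug-metabolising and 9 of 20 NRF2 and glutathione genes fell on HFHC, list calls that held with an estimated correlation (adjusted p = 0.0306 and 0.0306). Of the bile acid genes 10 of 17 fell and of the cholangiocyte and progenitor markers 8 of 11 rose, list calls that were lost with it (adjusted p = 0.0742 and 0.302). Cyp2c50 fell from 139 ± 54.7 to 3.32 ± 1.06 RPKM (log2 fold change -4.98 ± 0.26, -5.07 scaled, adjusted p = 1.11e-06). Gstm3 fell from 718 ± 38.3 to 65.0 ± 6.72 RPKM (log2 fold change -3.45 ± 0.18, -3.63 scaled, adjusted p = 1.11e-06). Cd24a, a surface protein of hepatic progenitors, rose from 3.43 ± 0.884 to 22.7 ± 4.82 RPKM (log2 fold change 2.42 ± 0.26, 2.21 scaled, adjusted p = 9.03e-05), and Lepr, the leptin receptor, from 1.16 ± 0.257 to 13.0 ± 3.94 RPKM (log2 fold change 2.66 ± 0.19, 2.42 scaled, adjusted p = 9.79e-06). limma called 3405 genes higher and 651 lower on the deposited values, 1509 and 889 on the scaled ones, 1503 and 1058 after quantile normalization, and 1509 and 648 on both. At least 99.7% of the genes called higher, and of those called lower, on both scales had the same sign within each set. They too were chosen by pooled calls. The median of all genes was 0.18 and 0.30 within the sets. Quantile normalization ended the calls of the peroxisomal, PPAR alpha target and acute phase lists. The count of 4056 was 2512 without Lampe1 HFHC 2 and 2602 without Lampe1 chow 3. Large rises included Igdcc4, an immunoglobulin superfamily gene (0.437 ± 0.212 against 8.45 ± 0.390 RPKM, 2.45 scaled), Psat1 (8.18 ± 3.57 against 51.7 ± 15.4 RPKM, 2.36 scaled) and alpha-fetoprotein, Afp (4.19 ± 0.242 against 29.6 ± 17.6 RPKM, 2.18 scaled).

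Drug-metabolising enzymes counted 15 lower of 19 (15 as deposited, 16 adjusted over the list alone). Their median was -2.37 (-2.44 and -2.28), with camera adjusted p = 4.10e-23 and adjusted p = 0.0306 with an estimated correlation. NRF2 and glutathione genes counted 9 lower of 20 (9 as deposited, 9 adjusted over the list alone). Their median was -0.61 (-0.59 and -0.80), with camera adjusted p = 1.67e-11 and adjusted p = 0.0306 with an estimated correlation. Bile acid genes counted 10 lower of 17 (10 as deposited, 10 adjusted over the list alone). Their median was -1.15 (-1.52 and -1.17), with camera adjusted p = 1.57e-14 and adjusted p = 0.0742 with an estimated correlation. Baat fell from 53.2 ± 6.39 to 12.6 ± 2.29 RPKM (-2.16 scaled), and the sterol hydroxylase Cyp8b1 from 62.9 ± 19.9 to 8.34 ± 4.26 RPKM (-2.96 scaled). Male-biased genes counted 10 lower of 17 (10 as deposited, 10 adjusted over the list alone). Their median was -1.2 (-0.96 and -1.53), with camera adjusted p = 1.32e-08 and adjusted p = 0.137 with an estimated correlation. Hepatocyte markers counted 1 higher and 8 lower of 16 (1 and 8 as deposited, 1 and 8 adjusted over the list alone). Their median was -0.85 (-0.66 and -0.82), with camera adjusted p = 1.32e-08 and adjusted p = 0.147 with an estimated correlation. Peroxisomal genes counted 0 higher and 3 lower of 32 (2 and 3 as deposited, 2 and 3 adjusted over the list alone). Their median was -0.22 (-0.42 and -0.10), with camera adjusted p = 0.00910 and adjusted p = 0.763 with an estimated correlation. This call was lost without Lampe1 HFHC 1, where adjusted p reached 0.332. PPAR alpha targets counted 1 higher and 4 lower of 23 (1 and 4 as deposited, 1 and 4 adjusted over the list alone). Their median was -0.33 (-0.44 and -0.18), with camera adjusted p = 0.000703 and adjusted p = 0.302 with an estimated correlation. Cholesterol biosynthesis genes counted 5 lower of 24 (5 as deposited, 4 adjusted over the list alone). Their median was -0.40 (-0.29 and -0.80), with camera adjusted p = 1.63e-05 and adjusted p = 0.511 with an estimated correlation. Cholangiocyte and progenitor markers counted 8 higher of 11 (8 as deposited, 9 adjusted over the list alone). Their median was 1.26 (1.16 and 1.25), with camera adjusted p = 0.000246 and adjusted p = 0.302 with an estimated correlation. Matrix and stellate cell markers counted 7 higher of 20 (12 as deposited, 13 adjusted over the list alone). Their median was 0.40 (0.39 and 0.45), with camera adjusted p = 0.0203 and adjusted p = 0.763 with an estimated correlation. This call was lost without Lampe1 chow 3 or Lampe1 HFHC 2, where adjusted p reached 0.0651. Endothelial markers counted 4 higher of 13 (10 as deposited, 10 adjusted over the list alone). Their median was 0.28 (0.34 and 0.21), with camera adjusted p = 0.0398 and adjusted p = 0.612 with an estimated correlation. This call was lost without Lampe1 chow 1 or Lampe1 HFHC 1, where adjusted p reached 0.0963. Kupffer cell markers counted 1 lower of 13 (1 as deposited, 0 adjusted over the list alone). Their median was -0.47 (-0.64 and -0.51), with camera adjusted p = 0.000907 and adjusted p = 0.459 with an estimated correlation. Clec4f fell from 28.5 ± 6.69 to 18.6 ± 1.36 RPKM (-0.74 scaled), a call lost without a filter, with a library set term (adjusted p = 0.0504), and without Lampe1 chow 3, Lampe1 HFHC 1, Lampe1 HFHC 2 or Lampe1 HFHC 3, where adjusted p reached 0.155. Alas2 fell as the only erythroid gene (-2.08 scaled, list camera adjusted p = 0.00902, and adjusted p = 0.134 with an estimated correlation). Acute phase genes had a call, lower, on the deposited values alone (camera adjusted p = 0.0109, and adjusted p = 0.242 with an estimated correlation, lost without Lampe1 chow 1, where adjusted p reached 0.0600).

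The log2 response to HFHC was lower in Lampe1 than in wild type for 9 of 19 drug-metabolising and 8 of 17 bile acid genes and higher for 6 of 11 progenitor markers. These list calls, like the other interaction calls of lists, were lost with an estimated correlation (adjusted p = 0.166, 0.166 and 0.223). Akr1c6, a hydroxysteroid dehydrogenase, averaged 303 ± 43.0 and 399 ± 25.2 RPKM in wild type and 259 ± 37.0 and 27.2 ± 2.51 RPKM in Lampe1 on chow and HFHC (interaction log2 fold change -3.61 ± 0.20, -3.68 scaled, adjusted p = 7.90e-06). Cyp1a2 averaged 299 ± 16.1 and 309 ± 32.8 RPKM in wild type and 289 ± 26.2 and 63.2 ± 7.51 RPKM in Lampe1 (-2.22 ± 0.18, -2.31 scaled, adjusted p = 7.44e-05), and Thrsp 151 ± 55.0 and 349.8 ± 122 RPKM in wild type and 44.5 ± 6.03 and 14.3 ± 8.86 RPKM in Lampe1 (-2.92 ± 0.53, -2.98 scaled, adjusted p = 0.00570). Cd24a averaged 1.15 ± 0.769 and 0.880 ± 0.440 RPKM in wild type and 3.43 ± 0.884 and 22.7 ± 4.82 RPKM in Lampe1 (2.58 ± 0.37, 2.43 scaled, adjusted p = 0.00179). limma gave a positive interaction for 853 genes and a negative one for 380 on the deposited values, 529 and 417 on the scaled ones, 676 and 554 after quantile normalization, and 528 and 360 on both. Every gene called on both scales had the same sign within both sets, though chosen by its pooled call. The median of all genes was 0.08 and 0.26 within the sets. Quantile normalization ended the calls of the peroxisomal, PPAR alpha target, gluconeogenesis, acute phase and erythroid lists. The count of 1233 was 702 without Lampe1 HFHC 2, 761 without Lampe1 chow 3 and 2788 with sample weights.

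Here higher and lower stand for a positive and a negative interaction. Cholesterol biosynthesis genes counted 8 lower of 24 (8 as deposited, 15 adjusted over the list alone). Their median was -1.17 (-1.29 and -1.23), with camera adjusted p = 8.10e-15 and adjusted p = 0.223 with an estimated correlation. Members included Idi1 (-1.73 ± 0.30, -1.82 scaled) and Insig1 (-1.31 ± 0.32, -1.40 scaled, lost without WT HFHC 1, WT HFHC 3 or Lampe1 HFHC 2, where adjusted p reached 0.0578). Lipogenesis genes counted 5 lower of 21 (5 as deposited, 5 adjusted over the list alone). Their median was -0.82 (-1.04 and -0.64), with camera adjusted p = 2.23e-08 and adjusted p = 0.166 with an estimated correlation. Members included Elovl5 (-1.44 ± 0.30, -1.53 scaled) and the transcription factor Mlxipl (-1.08 ± 0.22, -1.16 scaled). Bile acid genes counted 1 higher and 8 lower of 17 (1 and 8 as deposited, 1 and 11 adjusted over the list alone). Their median was -1.34 (-1.48 and -1.2), with camera adjusted p = 3.80e-11 and adjusted p = 0.166 with an estimated correlation. Members included Baat (-2.23 ± 0.20, -2.29 scaled) and Slc27a5 (-2.05 ± 0.27, -2.12 scaled). Drug-metabolising enzymes counted 0 higher and 9 lower of 19 (1 and 9 as deposited, 2 and 13 adjusted over the list alone). Their median was -1.42 (-2.06 and -1.25), with camera adjusted p = 5.38e-11 and adjusted p = 0.166 with an estimated correlation. Hepatocyte markers counted 0 higher and 4 lower of 16 (1 and 4 as deposited, 1 and 4 adjusted over the list alone). Their median was -0.75 (-0.94 and -0.60), with camera adjusted p = 3.25e-06 and adjusted p = 0.223 with an estimated correlation. Male-biased genes counted 0 lower of 17 (0 as deposited, 5 adjusted over the list alone, limma, 7 at an unadjusted p under 0.05). Their median was -0.62 (-0.48 and -1.24), with camera adjusted p = 0.000115 and adjusted p = 0.238 with an estimated correlation. Cholangiocyte and progenitor markers counted 6 higher of 11 (6 as deposited, 8 adjusted over the list alone). Their median was 1.5 (1.46 and 1.28), with camera adjusted p = 2.46e-05 and adjusted p = 0.223 with an estimated correlation. Members included Krt23 (1.75 ± 0.25, 1.53 scaled). Acute phase genes counted 0 higher and 4 lower of 22 (1 and 5 as deposited, 1 and 5 adjusted over the list alone). Their median was -0.13 (-0.21 and -0.27), with camera adjusted p = 0.00852 and adjusted p = 0.223 with an estimated correlation. Before the median of all genes was subtracted, that median was 0.02, and the mean was -0.40. Further lists with a negative call were peroxisomal genes (camera adjusted p = 0.0101, and adjusted p = 0.709 with an estimated correlation, lost without Lampe1 HFHC 1, where adjusted p reached 0.216), PPAR alpha targets (camera adjusted p = 0.00692, and adjusted p = 0.378 with an estimated correlation), Kupffer cell markers (camera adjusted p = 0.00349, and adjusted p = 0.384 with an estimated correlation) and Alas2 as the erythroid gene (camera adjusted p = 0.0206, and adjusted p = 0.223 with an estimated correlation). Interferon-stimulated genes (camera adjusted p = 0.0128, and adjusted p = 0.223 with an estimated correlation, lost without Lampe1 HFHC 1, where adjusted p reached 0.0548) and gluconeogenesis and glycolysis genes (camera adjusted p = 0.0166, and adjusted p = 0.384 with an estimated correlation, lost without Lampe1 chow 3, where adjusted p reached 0.0534) were also called negative. The matrix list had a positive call on the scaled values alone (adjusted p = 0.0428, and 0.0594 as deposited). Single genes with a clear interaction outside these lists included the glutamate transporter Slc1a2 (-3.40 ± 0.26, -3.39 scaled), the ammonium transporter Rhbg (-2.58 ± 0.24, -2.53 scaled), Crtap, a collagen-modifying protein (1.80 ± 0.15, 1.71 scaled), and Igdcc4 (2.74 ± 0.16, 2.47 scaled). For Acox1 the interaction was 0.26 ± 0.30, 0.17 scaled (adjusted p = 0.620).

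The genotype calls overlapped between the diets, in comparisons that share no library. Of the genes called higher in Lampe1, 7093 were called on both diets against 5559.5 for independent lists of the same lengths, and of those called lower 370 against 31.0. On the scaled values the shared counts were 1722 against 687 and 1168 against 262. Of the diet calls in wild type and in Lampe1, 14 higher genes were shared against 12.6 for independent lists, with 9 called in opposite directions, and 23 lower genes against 2.30, with 3 opposite. On the scaled values these were 12 against 5.86 and 29 against 4.63. The shared count of diet effects moved by more than 1.5 times when 1 library was left out. For higher genes it was 5 without WT chow 1 or WT chow 2, 7 without WT HFHC 3, 8 without WT HFHC 2, and 9 without Lampe1 chow 3 or Lampe1 HFHC 2. For lower genes it was 11 without WT chow 1 and 14 without WT chow 2.

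**Figure D3:**
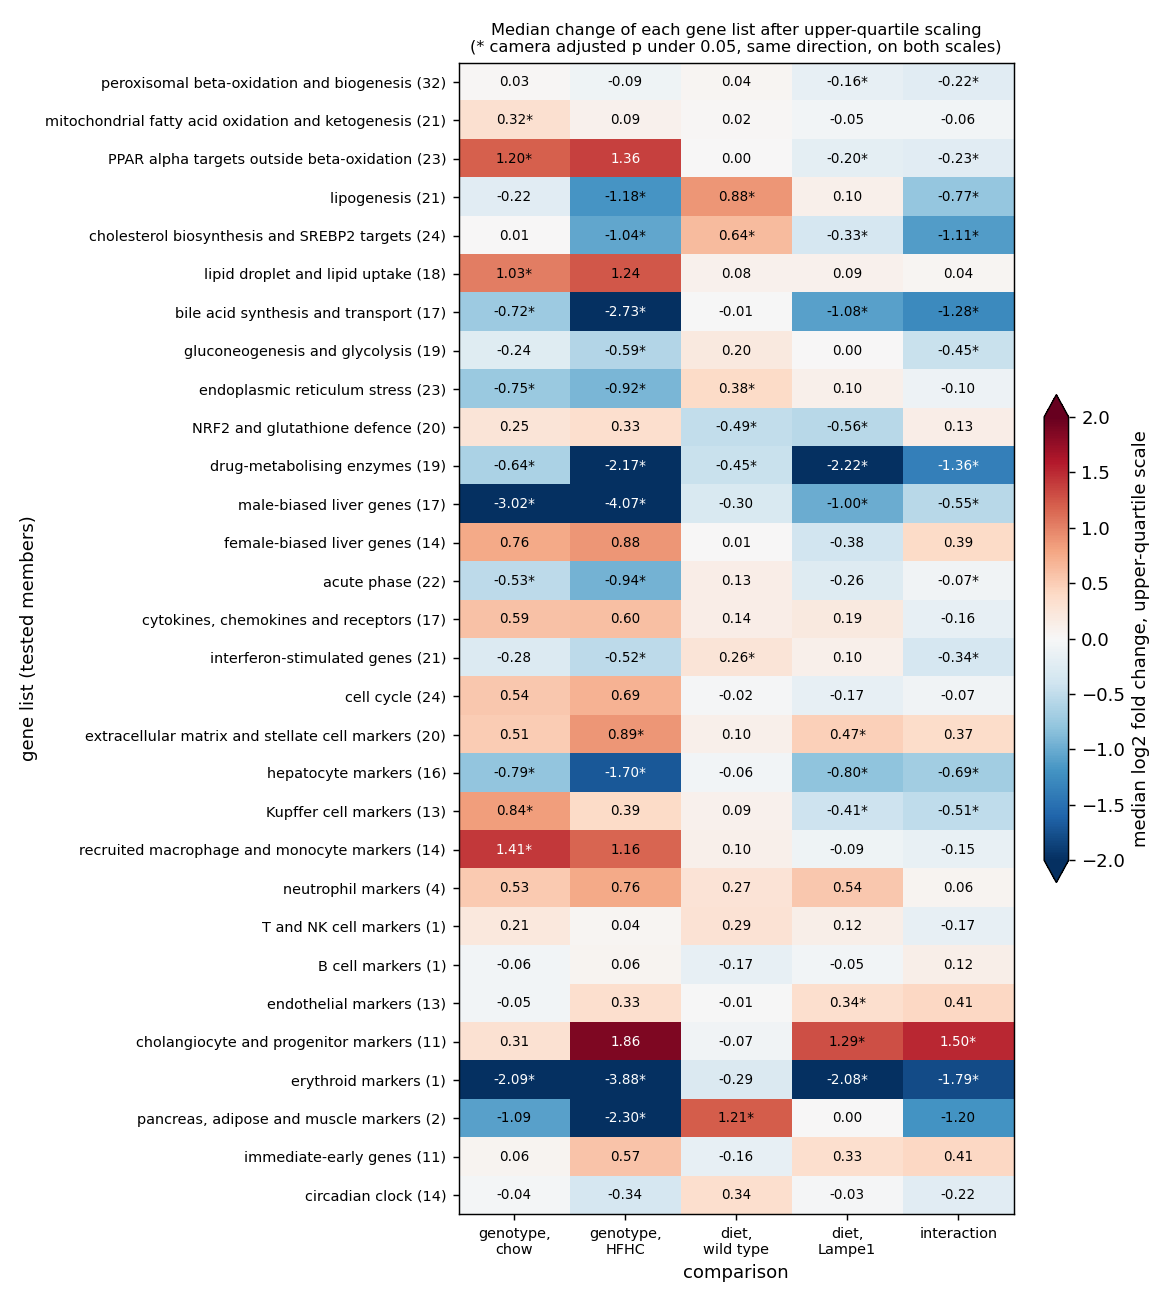
Heat map of the median log2 fold change of the 30 gene lists (vertical) after upper-quartile scaling in the 5 contrasts (horizontal), with the colour limited to values between -2 and 2 and an asterisk where camera gave an adjusted p under 0.05 in the same direction on both scales. The male-biased list has medians of -3.02 and -4.07 for the genotype on chow and HFHC, and the cholangiocyte and progenitor list 1.29 for the diet in Lampe1.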

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

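The tests chosen after the result was seen were the scaling without the 100 most abundant rows, the count of rows seen in 1 library set only, the 6 tests of swapped labels, and, for the cholangiocyte and progenitor list, the duct markers and the upper-quartile scaling.

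The diet response differed between the genotypes, by the interaction test, for 1233 genes. Among the genes followed through the alternatives, 54 had an interaction past the threshold on both scales. The interaction log2 fold changes below 0 were Cyp2c50 -4.63, Akr1c6 -3.61, Slc1a2 -3.40, Cyp2c38 -3.17, Thrsp -2.92, Cyp8b1 -2.91, Orm3 -2.80, Serpina3k -2.77, Cyp2c29 -2.60, Rhbg -2.58, Baat -2.23, Cyp1a2 -2.22, Gck -2.05, Slc27a5 -2.05, Apoa4 -2.05, Hpd -2.01, Slc17a8 -1.99, Fitm1 -1.83, Idi1 -1.73, Serpina1a -1.60, Saa4 -1.58, Elovl5 -1.44, Cyp2c70 -1.40, Ugt2b1 -1.36, Nsdhl -1.31, Insig1 -1.31, Gstm2 -1.29, Sult1d1 -1.27, Cyp27a1 -1.2, Hcn3 -1.17, Fabp2 -1.15, Mlxipl -1.08, Gstm3 -1.07, Apoh -1.0, Ebp -0.93, Phyh -0.91, Fah -0.85, Cat -0.81 and Serpina3n -0.76. Those above 0 were Igdcc4 2.74, Cd24a 2.58, Lepr 2.53, Psat1 2.44, Crtap 1.80, Krt23 1.75, Gstp1 1.67, Bicc1 1.65, Fabp4 1.34, Mcm2 1.18, Cd9 1.10, Acot2 1.02, Ephx1 0.84, Abcc3 0.79 and Ccne1 0.74. The Fabp4 call was lost without WT chow 1, Lampe1 chow 3 or Lampe1 HFHC 2, where adjusted p reached 0.0563.

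Of the 30 lists, 14 differed in their diet response between the genotypes by camera on both scales, and 0 of these calls held with an estimated correlation (6 of 30 had an unadjusted p under 0.05 with it). Their medians relative to all genes were erythroid markers -1.96, drug-metabolising enzymes -1.42, bile acid synthesis and transport -1.34, cholesterol biosynthesis and SREBP2 targets -1.17, lipogenesis -0.82, hepatocyte markers -0.75, male-biased liver genes -0.62, Kupffer cell markers -0.58, gluconeogenesis and glycolysis -0.51, interferon-stimulated genes -0.38, PPAR alpha targets outside beta-oxidation -0.28, peroxisomal beta-oxidation and biogenesis -0.28, acute phase -0.13, cholangiocyte and progenitor markers 1.5.

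With the diet labels drawn again within each genotype, 8 of 100 draws, the real one included, gave at least 1233 interaction genes (highest 3209). This does not decide whether chance can be excluded. All 8 kept the Lampe1 diet groups whole, some with labels exchanged, as 12 draws did, and so held that diet effect or its reverse. The other draws gave at most 255. For the 4 group contrasts 3 samples against 3 make 10 splits, too few for a share under 0.05. The real split, as the only 1 with so many genes in each case, gave 8095 genes for the genotype on chow against a highest other of 0, 9056 against 3 on HFHC, 82 against 3 for the diet in wild type and 4056 against 4 for the diet in Lampe1.

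Most tested genes were higher in Lampe1 than in wild type on the deposited values, with median log2 shifts of 0.51 on chow and 0.66 on HFHC. The library set was argued against as the whole cause, since the shift within a set was 0.40 to 0.68, and so was noise near the filter, since the 2220 genes with a mean of at least 20 RPKM shifted by 0.37 and 0.45. A few abundant genes taking a smaller share may account for part of it: scaling without the 100 most abundant rows left 0.245 on chow and 0.310 on HFHC, on both sides of the bound of 0.25, which decides nothing. Upper-quartile and quantile scaling centre the genes by construction and do not decide either. A general rise with the genotype stays open and untested, because RPKM give no amount of RNA per cell.

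The 2 library sets cut across the groups, and no biological explanation was tested. In the high set 41 rows without a symbol averaged at least 20 RPKM while they were listed at 0 in all 6 libraries of the low set (0 rows the other way), and they held 18.7 to 26.0% of the RPKM, which is consistent with processing by the authors that differed between the sets. With the diet labels of WT chow 3 and WT HFHC 3, or of Lampe1 chow 1 and Lampe1 HFHC 1, exchanged, 3 genes passed in place of 82 and 4 in place of 4056, against swapped labels. Of genes chosen without that pair, as called for the diet in the other genotype and apart by at least 1 log2 unit the same way in the other 4 libraries, 89.1% of 46 (median 0.92) and 95.7% of 23 (median 1.43) differed within the pair in the direction of the labels, which also argues against a swap. A first test on the lower diet genes of the other genotype gave a median of 0.64 in Lampe1 (82.5% of 40 genes higher on chow) and -0.10 in wild type (38.3% of 240), where it decides nothing because these genes hardly responded, with medians from -0.11 to 0.16 over the 9 pairs.

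The cholangiocyte and progenitor list was higher on HFHC than on chow in Lampe1, with a median log2 fold change of 1.5 not relative to all genes. This call was lost with an estimated correlation (adjusted p = 0.302). Scaling and the library set were argued against as its cause, with such medians of 1.29 after upper-quartile scaling and 1.33 and 1.54 within the sets. More bile duct cells cannot be told from expression in other cells. The 6 duct markers had a median of 0.69 and the other members 2.39. Higher on both scales were Epcam (1.17 ± 0.29), Hnf1b (0.80 ± 0.11) and Spp1 (1.96 ± 0.35). Krt7 (0.42 ± 0.38), Krt19 (0.47 ± 0.28) and Sox9 (0.58 ± 0.23) did not pass, at levels near the filter.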

How the results depend on the processing

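The alternatives added after the data were seen were the library set term, each library set alone, genes listed at 0 left out, and scaling without the 100 most abundant rows. Of 229 gene results (Acox1 between genotypes is given apart), 208 passed the threshold as reported and 127 of these passed under each setting run for them (27 settings, of which the stricter filter covered 198 results and the 6 samples of a comparison 197), and Ttr on chow alone of the 208 changed sign. Without a filter and with the highest row per symbol, all 5 counts and 4 overlaps stayed within 1.5 times. The unknown absolute depth limits what can be said of low genes. Counts are of genes past the threshold and of shared genes, and Acox1 is the log2 fold change between genotypes, given where it passed the threshold or, with the high set, changed sign.

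A pseudocount of 0.1 RPKM gave -0.50 for Acox1 on chow. The stricter filter gave 4567 for the genotype on chow, 5070 for the genotype on HFHC, 2280 for the Lampe1 diet, 814 for the interaction and 3885 for the higher genotype overlap. Quantile normalization gave 2801 for the genotype on chow, 5427 for the genotype on HFHC, 2561 for the Lampe1 diet, 1154 for the higher genotype overlap and 1105 for the lower genotype overlap. Upper-quartile scaling gave 3472 for the genotype on chow, -1.08 for Acox1 on chow, 5888 for the genotype on HFHC, -0.91 for Acox1 on HFHC, 2398 for the Lampe1 diet, 1722 for the higher genotype overlap and 1168 for the lower genotype overlap. Only the 6 samples of a comparison gave -0.50 for Acox1 on chow and 52 for the wild-type diet. They gave 5 for the higher diet overlap (6.38 for independent lists) and 15 for the lower diet overlap (1.19). Sample weights gave -0.53 for Acox1 on chow, 425 for the wild-type diet and 2788 for the interaction. They gave 133 for the higher diet overlap (132.24 for independent lists) and 53 for the lower diet overlap (9.84). A library set term gave -0.50 for Acox1 on chow. Upper-quartile scaling and a library set term gave 3646 for the genotype on chow, -1.08 for Acox1 on chow, -0.91 for Acox1 on HFHC, 2199 for the Lampe1 diet, 1805 for the higher genotype overlap and 1239 for the lower genotype overlap. Only the low set gave 5637 for the genotype on HFHC, -0.89 for Acox1 on HFHC, 16 for the wild-type diet, 636 for the Lampe1 diet, 96 for the interaction, 3965 for the higher genotype overlap, 2 for the higher diet overlap and 3 for the lower diet overlap. Only the high set gave 2795 for the genotype on chow, 0.0889 for Acox1 on HFHC, 15 for the wild-type diet, 1477 for the Lampe1 diet, 120 for the interaction, 2413 for the higher genotype overlap, 216 for the lower genotype overlap, 0 for the higher diet overlap and 12 for the lower diet overlap. Genes listed at 0 left out gave -0.50 for Acox1 on chow. Scaling without the 100 most abundant rows gave 4680 for the genotype on chow, -0.85 for Acox1 on chow, -0.69 for Acox1 on HFHC, 2547 for the Lampe1 diet, 3287 for the higher genotype overlap and 724 for the lower genotype overlap. A fold of at least 2 gave 1297 for the genotype on chow, 3219 for the genotype on HFHC, 43 for the wild-type diet, 465 for the Lampe1 diet and 468 for the interaction. The lower counts under the stricter filter and single sets follow from fewer genes or samples, and those with a fold minimum from the added criterion. For the other settings the cause was not tested.

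These log2 fold changes of genes lay on the other side of 0 from the deposited value. Quantile normalization gave 0.87 (Cyp3a11, genotype on chow), 0.24 (Ttr, genotype on chow), -0.12 (Acaa2, genotype on HFHC), 1.02 (Fabp1, genotype on HFHC) and 0.00144 (Acaa1b, diet in wild type). Upper-quartile scaling gave -0.31 (Acaa2, genotype on chow), -0.16 (Fabp1, genotype on chow), -0.0322 (Scd1, genotype on chow), -0.21 (Gstm1, genotype on chow), -0.59 (Acaa2, genotype on HFHC) and -0.00935 (Acox1, diet in wild type). Upper-quartile scaling and a library set term gave -0.31 (Acaa2, genotype on chow), -0.16 (Fabp1, genotype on chow), -0.0322 (Scd1, genotype on chow), -0.21 (Gstm1, genotype on chow), -0.59 (Acaa2, genotype on HFHC) and -0.0661 (Acox1, diet in wild type). Only the low set gave -0.0804 (Acaa2, genotype on HFHC), 0.56 (Cyp4a14, diet in wild type), -0.10 (Acox1, diet in Lampe1) and -0.48 (Acox1, genotype by diet interaction). Only the high set gave 0.12 (Cyp3a11, genotype on chow) and -0.20 (Acox1, diet in wild type). Scaling without the 100 most abundant rows gave -0.0738 (Acaa2, genotype on chow) and -0.38 (Acaa2, genotype on HFHC). For 3 list calls camera turned direction and did not pass, while the median relative to all genes stayed below 0: -0.00351 against -0.16 as deposited (lipogenesis, genotype on chow) and -0.19 against -0.47 as deposited (acute phase, genotype on chow) with quantile normalization, and -0.0449 against -0.28 as deposited (peroxisomal beta-oxidation and biogenesis, genotype by diet interaction) with only the high set. The cause was not tested.

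Of the 68 camera list calls, 22 were lost and 2 turned with quantile normalization, 17 were lost with the stricter filter, 12 with only the low set, 7 with only the high set, where 1 turned, 11 with upper-quartile scaling and a library set term, 9 with upper-quartile scaling alone, 5 without a filter, 5 with sample weights, 4 with only the 6 samples, 4 with scaling without the 100 most abundant rows, 3 with the pseudocount, 2 with the replicate block, 56 with the estimated correlation, 0 with a library set term, 0 with the highest row per symbol, and 4 with genes listed at 0 left out, of which 3 were calls of the pancreas, adipose and muscle list, then without Cfd, and 1 of the mitochondrial list on HFHC. Quantile normalization took the lists called higher and lower from 5 and 11 to 11 and 3 for the genotype on chow, from 2 and 13 to 8 and 7 on HFHC, from 5 and 4 to 9 and 2 for the diet in wild type, from 3 and 11 to 4 and 8 in Lampe1 and from 1 and 13 to 2 and 8 for the interaction. The calls it ended are named with each comparison.

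Leaving out 1 library at a time gave 7083 to 8218 genes for the genotype on chow, 8468 to 9120 on HFHC, 31 to 101 for the diet in wild type, 2512 to 4447 in Lampe1 and 702 to 1269 for the interaction. The genotype overlaps ranged over 6387 to 7063 and 309 to 394, and the diet overlaps over 5 to 21 and 11 to 26. The lists past the threshold numbered 15 to 18, 13 to 16, 6 to 10, 12 to 16 and 13 to 17. Acox1 on chow ranged over -0.65 to -0.41 and passed without WT chow 2, WT HFHC 2, Lampe1 HFHC 1 or Lampe1 HFHC 3, and on HFHC over -0.45 to -0.00918. Acox1, diet in wild type ranged over -0.0549 to 0.23. Cyp3a11, genotype on chow ranged over -0.20 to 0.0529. Fabp1, genotype on HFHC ranged over -0.31 to 0.0807. Hspa5, genotype on chow ranged over -0.66 to 0.0209. Libraries that moved a count by more than 1.5 times were WT chow 1 and WT chow 2 (both 31), WT HFHC 1 (53) and WT HFHC 3 (44) for the diet in wild type, and Lampe1 HFHC 2 and Lampe1 chow 3 for the diet in Lampe1 (2512 and 2602) and the interaction (702 and 761).

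Replicate numbers were not taken as pairs, as not all 18 same-number pairs had deviations correlated above 0.1, which does not exclude pairing. Of them 6 did (range -0.32 to 0.47), or 11 (-0.0475 to 0.49) with the library set taken out, checked after the data were seen. Yet 7 of 12 samples, or 8, correlated best with their own number, so it may mark something shared. Within-set contrasts mix replicate numbers. With the replicate block the counts were 8321, 9204, 114, 4237 and 1251, the diet overlap, higher, 22 (20.2 for independent lists), and Acox1 on chow -0.50, now past the threshold. With an estimated correlation 1, 8, 1, 2 and 0 lists passed in the 5 contrasts. fry, which asks whether a list moves one way and not whether it differs from other genes, called 21, 24, 6, 10 and 6 lists. It gave the opposite direction for 3 of 11 lists that camera called lower for the genotype on chow and 1 of 13 on HFHC.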

Other observations

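Genes listed at 0 in some libraries were left out of the named genes, and H19 was chosen here after its values were seen. H19, a fetal liver RNA, was listed at 0.0970, 0 and 0.0410 in wild type on chow, 0.171, 0.151 and 0.121 in wild type on HFHC, 2.84, 2.30 and 0.896 in Lampe1 on chow and 13.4, 19 and 35.5 in Lampe1 on HFHC (RPKM, samples 1, 2 and 3 of each group).

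The clock genes Arntl and Npas2 had their highest value under number 1 of the labels and their lowest under number 3 in each of the 4 groups, with Arntl at 6.23, 5.04 and 1.86 in wild type on chow, 5.83, 4.21 and 1.31 in wild type on HFHC, 9.01, 3.87 and 0.858 in Lampe1 on chow and 6.44, 1.96 and 0.647 in Lampe1 on HFHC. Collection times are not stated, and no cause was tested.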
